A study of Mus musculus with 10 samples.

How the data were processed

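Gene expression was measured by poly-A RNA sequencing on an Illumina HiSeq instrument in 10 tumours of Hepa1-6 cells, a mouse hepatoma line, grown for 4 weeks under the skin of C57BL/6 mice. Per the series' design text, 5 tumours came from mice given vehicle and 5 from mice given GSK343, an inhibitor of the histone methyltransferase EZH2, and these are biological replicates. Titles beginning with G were taken as GSK343 and those beginning with C as vehicle. The second assignment rests on elimination between the 2 conditions. The labels' protocols also mention a control antibody and an antibody against asialo-GM1, which removes natural killer cells, but no label says which tumour received which, so the antibody could not enter any model.

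The authors' deposited table holds 1 value per gene and tumour, with no unit in its header. The deposited values were read as FPKM, fragments scaled by exon length and library size, from the values themselves. They summed to between 574547 and 623397 per tumour, and in genes with a single exon of more than 300 bases the products of value and length fell on steps of 19.8 to 26.2. If 1 step is 1 read, the libraries held 38.2 to 50.5 M reads (M, mega); this is an inference, and whole reads were not recovered. Per the submitters' processing notes, Trimmomatic 0.33, HISAT2 2.1.0, StringTie 1.3.3b and the mm10 genome were used. The options, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The table had 55020 lines for 54986 gene identifiers, of which 13 identifiers had more than 1 line. GENCODE mouse release M21 held 54165 of the identifiers, 52904 of them at the same coordinates, and supplied gene types and overlaps. A value of exactly 0 stood in 1 to 9 tumours for 166 lines whose mean was at least 1. Such a 0 can be a failed estimate and is described only as listed at 0. There were 10 further columns with no name and no values.

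From these values, log2(FPKM + 1) was tested between the groups with limma 3.58.1 (R 4.3.3), with an intensity trend, over the 14496 lines with a mean of at least 1 FPKM. A fold change on this scale understates the change of low genes. Calls were made at a Benjamini-Hochberg adjusted p under 0.05, two-sided. All 48 gene lists fixed before the data were examined were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry. A list's score in a tumour is the mean log2(FPKM + 1) of its tested members. Scores were compared by an exact two-sided permutation test over the 252 assignments of 5 of the 10 tumours, for which the smallest possible p is 0.00794. Adjustment over the list alone means Benjamini-Hochberg over the tested members of that list. The p of limma's gene test, of fry and of the permutation tests measures the spread between tumours. The depth of each library enters only through that spread. The p of camera at the preset correlation rests on the spread between genes and takes the members of a list as nearly independent. It does not measure the spread between tumours. No counting interval can be given for FPKM.

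Genes were named by a rule set before the data were examined. It takes Ezh2, Ezh1, Suz12, Eed, Cxcl10, Cxcl9, Ccl5, Hdac10, Ncr1, Klrk1, Ulbp1 and Raet1e. It adds the 10 largest changes in each direction among named genes past the threshold (the 5 with the smallest p where fewer than 5 pass) and up to 4 members with the smallest p of each list described. Predicted genes, pseudogenes, unnamed genes and antigen receptor segments stayed outside the second part. Where several lines shared a symbol, the one with the highest mean was used.

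Alternatives covered the filter, the pseudocount, scaling, the variance model, tumour weights, a leukocyte covariate, the replicate number as a block, the threshold, and each tumour left out in turn. Those added after the data were seen were summed lines of a gene identifier, genes with a listed 0 left out, 3 pairs of tumours left out, and a Y-linked covariate. The gene test was checked on data simulated from the means and spreads of the 14496 lines, each drawn independently. In these data 200 genes were changed, all taken from the more highly expressed lines. The test recovered 84% of genes changed 2-fold and 98% of genes changed 4-fold, and 5.21% of its calls were false. Genes of real tumours can move together, which the simulation leaves out. These rates therefore need not hold for the real data, nor for weakly expressed lines. Plots were drawn with matplotlib 3.10.9.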

Results

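The transcriptomes of 5 vehicle and 5 GSK343 Hepa1-6 tumours were compared to find which transcripts differed after treatment with the EZH2 inhibitor. Each tumour had between 13985 and 14714 lines at 1 FPKM or more, and the inferred depth was 38.2 to 50.5 M reads. Mitochondrial transcripts made up 7.17% and 7.11% of the FPKM sum in GSK343 replicates 3 and 5 and 2.63% to 5.05% in the other tumours.

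Few single genes separated the treatments, and most of those that did were higher after GSK343. Hsd17b12, a ketoacyl-CoA reductase of fatty acid elongation (ENSMUSG00000027195.10, mm10 chromosome 2, 94032689 to 94157964), rose from 20.5 ± 3.12 to 56.3 ± 4.61 FPKM (SD, n = 5 per group; log2 fold change 1.43, SE 0.105, limma adjusted p = 0.000696). Tnfrsf14, the receptor HVEM of the tumour necrosis factor receptor family (chromosome 4, 154921933 to 154928563), rose from 1.997 ± 0.708 to 7.18 ± 1.34 FPKM (limma adjusted p = 0.0226). Sirpb1b, a member of the signal-regulatory protein family of myeloid receptors, rose from 2.19 ± 0.431 to 5.60 ± 0.544 FPKM (limma adjusted p = 0.00548). Peak1, a pseudokinase linked to the cytoskeleton, fell from 8.09 ± 1.18 to 3.65 ± 0.481 FPKM (limma adjusted p = 0.0111), and Specc1l, a cytoskeletal crosslinking protein, fell from 8.76 ± 0.327 to 5.38 ± 0.711 FPKM (limma adjusted p = 0.0373). The groups did not overlap for any of these 5 genes.

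In all, 12 of 14496 lines passed the adjusted threshold, 10 higher and 2 lower in GSK343 tumours. Among them were Mir3091, which lies within Rps21 and whose reads cannot be told apart from it (0.00342 ± 0.000955 against 3.60 ± 1.43 FPKM, limma adjusted p = 0.00162), the protein-coding RP23-391A14.5 (3.59 ± 0.268 against 6.82 ± 1.17 FPKM), the small nuclear RNA Gm24407 (0.438 ± 0.0914 against 1.73 ± 0.516 FPKM) and 4 processed pseudogenes, whose reads may be shared with their parent genes. An unadjusted p under 0.05 was reached by 2547 lines, 1552 higher and 995 lower. As many were reached in 5 of 100 splits of the tumours into 5 and 5, the real one included, with 3386 lines in the highest other split. The groups did not overlap for 2.62% of lines, against 0.794% on average over all splits. How far single splits depart from that average was not counted, so the excess was not tested. The number of calls depended on single tumours. It was 98 without vehicle replicate 2 and 37 without GSK343 replicate 1. It was 6 without vehicle replicate 1, 5 without vehicle replicate 5, and 5 without vehicle replicate 6. It was 4 without GSK343 replicate 2, 3 without GSK343 replicate 3, 3 without GSK343 replicate 4, and 6 without GSK343 replicate 5. With median-of-ratios scaling or quantile normalization there were 7 calls, 5 higher and 2 lower. Specc1l lost its call in 8 of the 10 fits that left out a tumour, Tnfrsf14 in 6 and Peak1 in 2, while Hsd17b12 kept it in all 10. With the pan-leukocyte score as a covariate 2 of the 12 calls remained, Hsd17b12 and Mir3091, and the counts were 4 without GSK343 replicates 3 and 5 and 6 without vehicle replicates 1 and 3.

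**Figure D1:**
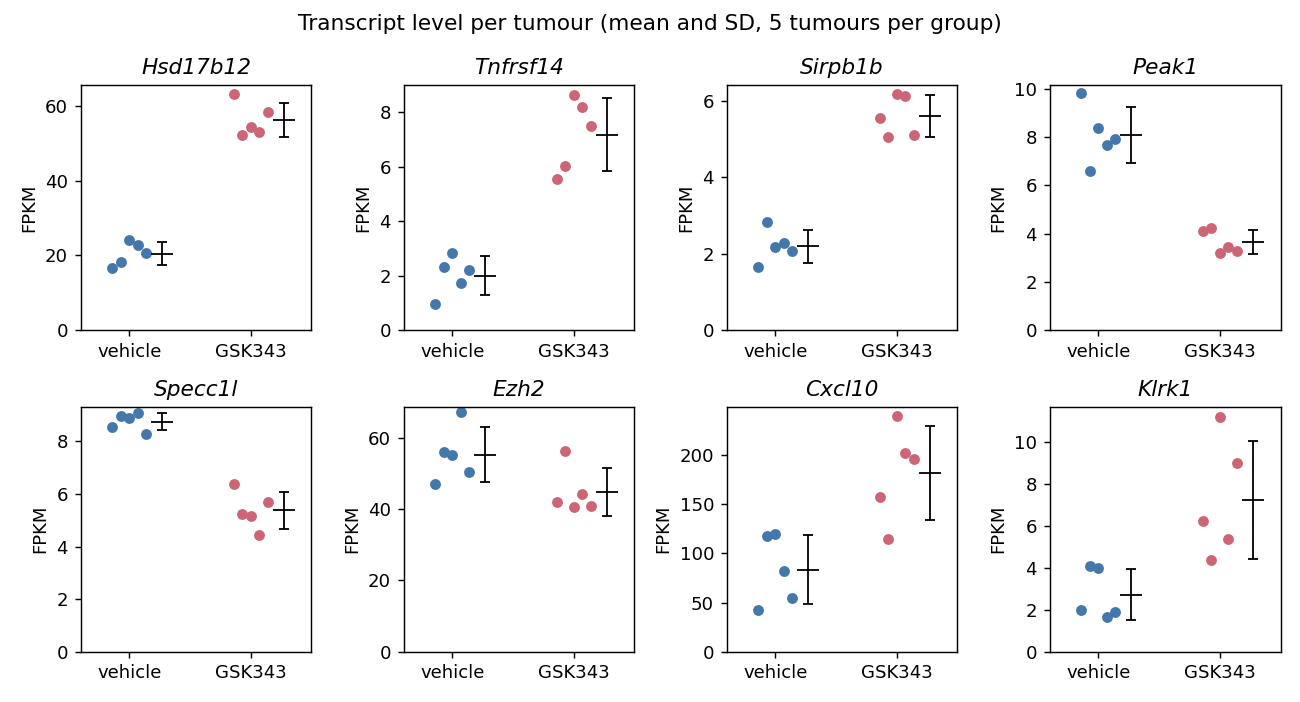
FPKM of 8 genes in each tumour (points), with the mean and SD of 5 tumours per group (black) on axes that start at 0. Hsd17b12, Tnfrsf14 and Sirpb1b lie higher in every GSK343 tumour than in any vehicle tumour, Peak1 and Specc1l lie lower, and the other genes did not pass the adjusted threshold.

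Named genes with the next smallest p in their direction, 1 higher and 3 lower, did not pass. Rnu3b4, a U3 small nucleolar RNA that overlaps Tex14, measured 1.56 ± 0.722 against 5.31 ± 1.305 FPKM (limma adjusted p = 0.0615). Slc25a1, the mitochondrial citrate carrier, measured 63.1 ± 2.39 in vehicle and 49.2 ± 1.89 FPKM in GSK343 tumours (limma adjusted p = 0.0578). Hnrnpc, an RNA-binding protein, measured 128 ± 25.8 and 78.8 ± 4.75 FPKM (limma adjusted p = 0.136), and Tuba4a, an alpha-tubulin, 41.0 ± 4.56 and 29.2 ± 3.31 FPKM (limma adjusted p = 0.167).

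The drug's target and its partners did not pass the test. Ezh2, the catalytic subunit of Polycomb repressive complex 2, measured 55.2 ± 7.65 FPKM in vehicle and 44.8 ± 6.60 FPKM in GSK343 tumours (SD, n = 5; log2 fold change -0.30, limma adjusted p = 0.233). The log2 fold changes of its paralog Ezh1 (-0.08), of Suz12 (-0.08) and of Eed (0.08) were near their standard errors of 0.0851, 0.0892 and 0.0843, and each changed sign under at least 1 alternative. The list of PRC2 subunits was not called (median log2 fold change -0.07, adjusted p = 0.225 by camera). Neither was the list of HOX and developmental regulators, common Polycomb targets (0.05, adjusted p = 0.404), of which 13 of 56 genes were expressed highly enough to test. The cyclin-dependent kinase inhibitors were not called either (-0.08, adjusted p = 0.206). The histone deacetylases fell as a list (median -0.19, adjusted p = 0.0163 by camera; adjusted p = 0.412 with an estimated correlation), although none of the 10 members passed, including Hdac10 at 5.08 ± 1.18 and 4.06 ± 0.577 FPKM.

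Interferon-response genes were higher in GSK343 tumours as lists. The interferon-stimulated genes rose (median log2 fold change 0.65, adjusted p = 5.03e-13 by camera; adjusted p = 0.399 with an estimated correlation), with 25 of 26 members higher. None passed over all genes tested, and 18 were higher when adjusted over the list alone. Oas2, an antiviral oligoadenylate synthetase, measured 1.64 ± 0.730 against 4.46 ± 0.634 FPKM (limma adjusted p = 0.0615), and Ifit3 5.66 ± 1.12 against 10.9 ± 3.55 FPKM. The list score lay higher in every GSK343 tumour than in any vehicle tumour (3.77 ± 0.268 against 4.41 ± 0.220, exact permutation p = 0.00794, adjusted 0.127). The interferon-gamma-induced genes rose as well (median 0.88, adjusted p = 6.29e-11; adjusted p = 0.399 with an estimated correlation), with 16 of 19 members higher adjusted over the list alone and none over all genes tested. Iigp1, an interferon-inducible GTPase, measured 85.6 ± 27.3 against 179 ± 54.0 FPKM, and Gbp6, a guanylate-binding protein, 10.5 ± 6.22 against 27.1 ± 6.03 FPKM.

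Chemokines that attract lymphocytes showed the same direction (median 0.88, adjusted p = 1.62e-06 by camera; adjusted p = 0.399 with an estimated correlation), with 6 of 9 members higher adjusted over the list alone and none over all genes tested. Cxcl10 and Cxcl9, ligands of the receptor CXCR3, measured 83.4 ± 35.2 against 182 ± 47.7 FPKM (limma adjusted p = 0.191) and 78.1 ± 36.5 against 169 ± 58.7 FPKM (limma adjusted p = 0.192). Cxcl11, another ligand of that receptor, measured 0.938 ± 0.537 against 4.67 ± 2.13 FPKM without overlap (limma adjusted p = 0.131). Without GSK343 replicates 3 and 5, the tumours with the highest mitochondrial share, the median of the list was 0.52. These tumours also had the highest scores of this list, 6.00 and 5.68. The same held for the natural killer cell, T cell, cytotoxic, immediate early and pan-leukocyte lists. A lower median of such a list without them therefore says nothing about library quality. Ccl5 measured 104 ± 69.2 against 179 ± 88.4 FPKM (limma adjusted p = 0.322), and vehicle replicate 2, at 225.9 FPKM, lay far above the other vehicle tumours.

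The natural killer cell list rose (median 0.83, adjusted p = 7.02e-07 by camera; adjusted p = 0.399 with an estimated correlation), with 5 of 15 tested members higher adjusted over the list alone and none over all genes tested. The median was 0.40 without GSK343 replicates 3 and 5, and 0.01 with the pan-leukocyte score as a covariate, which ended the call (adjusted p = 0.920 by camera). Klrk1, which encodes the activating receptor NKG2D, measured 2.73 ± 1.21 against 7.25 ± 2.81 FPKM without overlap (limma adjusted p = 0.189). Ncr1, which encodes the natural killer cell receptor NKp46, lay below the filter at 0.2996 ± 0.150 and 0.726 ± 0.504 FPKM. The ligands of NKG2D were not called (median 0.20, adjusted p = 0.269). Ulbp1 measured 3.01 ± 0.666 and 2.90 ± 0.690 FPKM, and Raet1e 1.11 ± 0.426 and 1.56 ± 0.340 FPKM.

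T cell genes rose as a list (median 0.65, adjusted p = 2.59e-07 by camera; adjusted p = 0.414 with an estimated correlation), but none of the 19 tested members passed, even adjusted over the list alone, and the list scores overlapped (2.72 ± 0.531 against 3.39 ± 0.524, exact permutation p = 0.0873). The median was 0.32 without GSK343 replicates 3 and 5 (adjusted p = 0.00580 by camera). Cd4 measured 1.76 ± 0.917 against 4.65 ± 2.20 FPKM. Cytotoxic effectors rose (median 0.73, adjusted p = 2.46e-06; adjusted p = 0.399 with an estimated correlation), with 1 of 14 members passing adjusted over the list alone. That member was Gzmc, a granzyme, at 2.87 ± 0.535 against 7.41 ± 2.81 FPKM (limma adjusted p = 0.136 over all genes). The median of the list was 0.43 without GSK343 replicates 3 and 5.

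Antigen presentation and myeloid genes were also higher. All 10 genes of the MHC class II list passed adjusted over the list alone, and none over all genes tested (median 0.87, adjusted p = 1.5e-07 by camera; adjusted p = 0.399 with an estimated correlation). Ciita, the class II transactivator, measured 4.70 ± 1.32 against 10.3 ± 2.70 FPKM. The MHC class I list rose (median 0.42, adjusted p = 3.53e-07; adjusted p = 0.399 with an estimated correlation), with 0 of 17 members passing adjusted over the list alone, and 11 at an unadjusted p under 0.05 in limma. Macrophage and monocyte genes rose (median 0.93, adjusted p = 9e-08; adjusted p = 0.399 with an estimated correlation), with 15 of 19 members higher adjusted over the list alone and none over all genes tested. Adgre1, which encodes the macrophage marker F4/80, measured 8.10 ± 5.17 against 16.3 ± 5.24 FPKM. The pan-leukocyte list moved with these lists (median 0.74, adjusted p = 6.1e-07; adjusted p = 0.399 with an estimated correlation), and vehicle replicates 2 and 3, at scores of 5.27 and 4.88, lay within the range of the GSK343 tumours, 4.86 to 5.64. With the pan-leukocyte score as a covariate, 8 lists were called in place of 26. The interferon-stimulated list (median 0.29, adjusted p = 6.12e-06 by camera) and the interferon-gamma-induced list (0.24, adjusted p = 0.00676) stayed called at the preset correlation, but not with an estimated correlation (adjusted p = 0.916 for both). The T cell list had a median of -0.13, the cytotoxic list -0.02, the macrophage list 0.03, the MHC class I list 0.03, the MHC class II list 0.09 and the lymphocyte-attracting chemokines 0.10, none of them called.

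**Figure D2:**
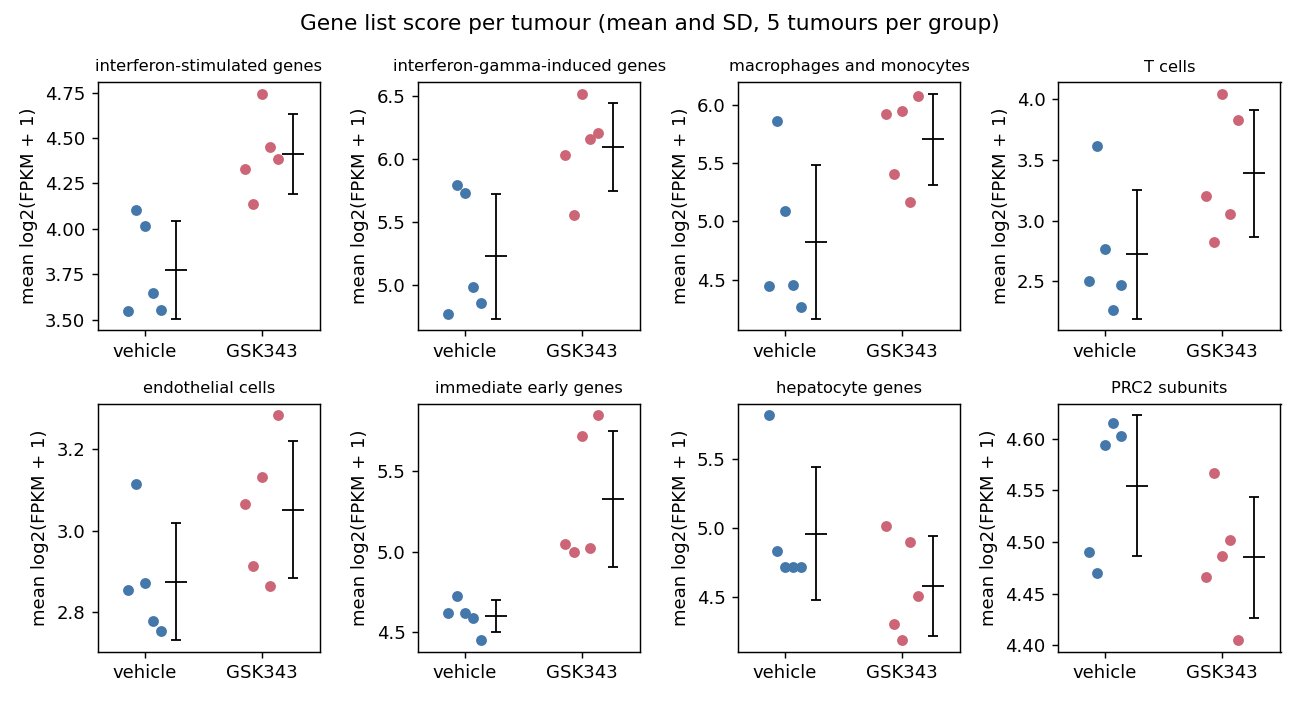
Score of 8 gene lists in each tumour (points, mean log2(FPKM + 1) of the tested members), with the mean and SD of 5 tumours per group (black). The interferon-stimulated scores separate the groups, the immediate early scores do so only while Junb is listed at 0 in vehicle replicate 2, and the T cell and macrophage scores overlap because 1 vehicle tumour lies among the GSK343 tumours.

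Fibroblast, immediate early, skeletal muscle and hepatocyte lists differed too. Fibroblast and extracellular matrix genes rose (median 0.55, adjusted p = 1.58e-09 by camera; adjusted p = 0.399 with an estimated correlation), with 13 of 20 members higher adjusted over the list alone and none over all genes tested. Postn, a matrix protein of activated fibroblasts, measured 62.5 ± 11.97 against 145 ± 73.3 FPKM. Immediate early genes rose (median 0.60, adjusted p = 1.78e-07; adjusted p = 0.399 with an estimated correlation), with 7 of 16 members higher adjusted over the list alone and none over all genes tested. Atf3, a stress-induced transcription factor, measured 26.4 ± 10 against 58.7 ± 26.9 FPKM. The immediate early score separated the groups (exact permutation p = 0.00794), but Junb is listed at 0 in vehicle replicate 2 because its value stands on another line, and with summed lines that tumour's score of 5.22 lay within the range of the GSK343 tumours (exact permutation p = 0.0317). The median of the list was 0.37 without GSK343 replicates 3 and 5, and 0.15 with the pan-leukocyte covariate, which ended the call (adjusted p = 0.0924 by camera), as it did for the fibroblast list (median 0.14, adjusted p = 0.0524). Skeletal muscle genes rose (median 1.42, adjusted p = 3.01e-07; adjusted p = 0.399 with an estimated correlation), with 5 of 13 members higher adjusted over the list alone and none over all genes tested. Myl1, a myosin light chain, measured 5.25 ± 3.60 against 20.8 ± 11.0 FPKM. The skeletal muscle scores overlapped (2.33 ± 1.09 against 3.81 ± 0.891). The median of that list was 1.02 without GSK343 replicates 3 and 5. With the pan-leukocyte covariate it was 1.88 and still called (adjusted p = 6.33e-11 by camera), though not with an estimated correlation (adjusted p = 0.916). Hepatocyte genes fell as a list (median -0.32, adjusted p = 0.00435; adjusted p = 0.509 with an estimated correlation), with no member passing. Apoa1 measured 79.7 ± 34.7 and 39.98 ± 16.1 FPKM. The hepatocyte list was not called without vehicle replicate 1 (median -0.11) or without vehicle replicates 1 and 3 (-0.15). Nor was it called with the pan-leukocyte covariate (-0.06) or the Y-linked covariate (-0.08). Its median was -0.21 without GSK343 replicates 3 and 5 and -0.13 with tumour weights.

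Of the 48 lists, 26 were called by camera, 20 higher and 6 lower, but none with an estimated correlation (smallest adjusted p = 0.399) and none by fry. With quantile normalization 21 were called higher and 3 lower. The lists called lower numbered 2 at a mean of at least 5 FPKM and 1 without vehicle replicates 1 and 3, where 20 and 21 were called higher. The other lists called higher were pericytes and smooth muscle, inhibitory receptors and regulatory T cells, dendritic cells, myeloid-attracting chemokines, neutrophils, B and plasma cells, and mast cells and basophils. The other lists called lower were keratinocytes, cytosolic ribosomal proteins, proliferation, and fetal liver and liver tumour genes. Endothelial cell genes were not called (median 0.23, adjusted p = 0.118). The lists of p53 targets, the unfolded protein response, mitochondrially encoded genes, sex-linked genes, heat shock, red blood cells, hypoxia and glycolysis, fatty acid oxidation, Wnt targets, acute-phase genes, replication-dependent histones, peripheral nerve, adipocytes, fatty acid synthesis, xenobiotic metabolism, epithelial-mesenchymal transition regulators and sterol biosynthesis were not called either. By list scores, 17 lists had an exact permutation p under 0.05, 16 higher and 1 lower in GSK343 tumours, and the smallest adjusted p was 0.127.

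**Figure D3:**
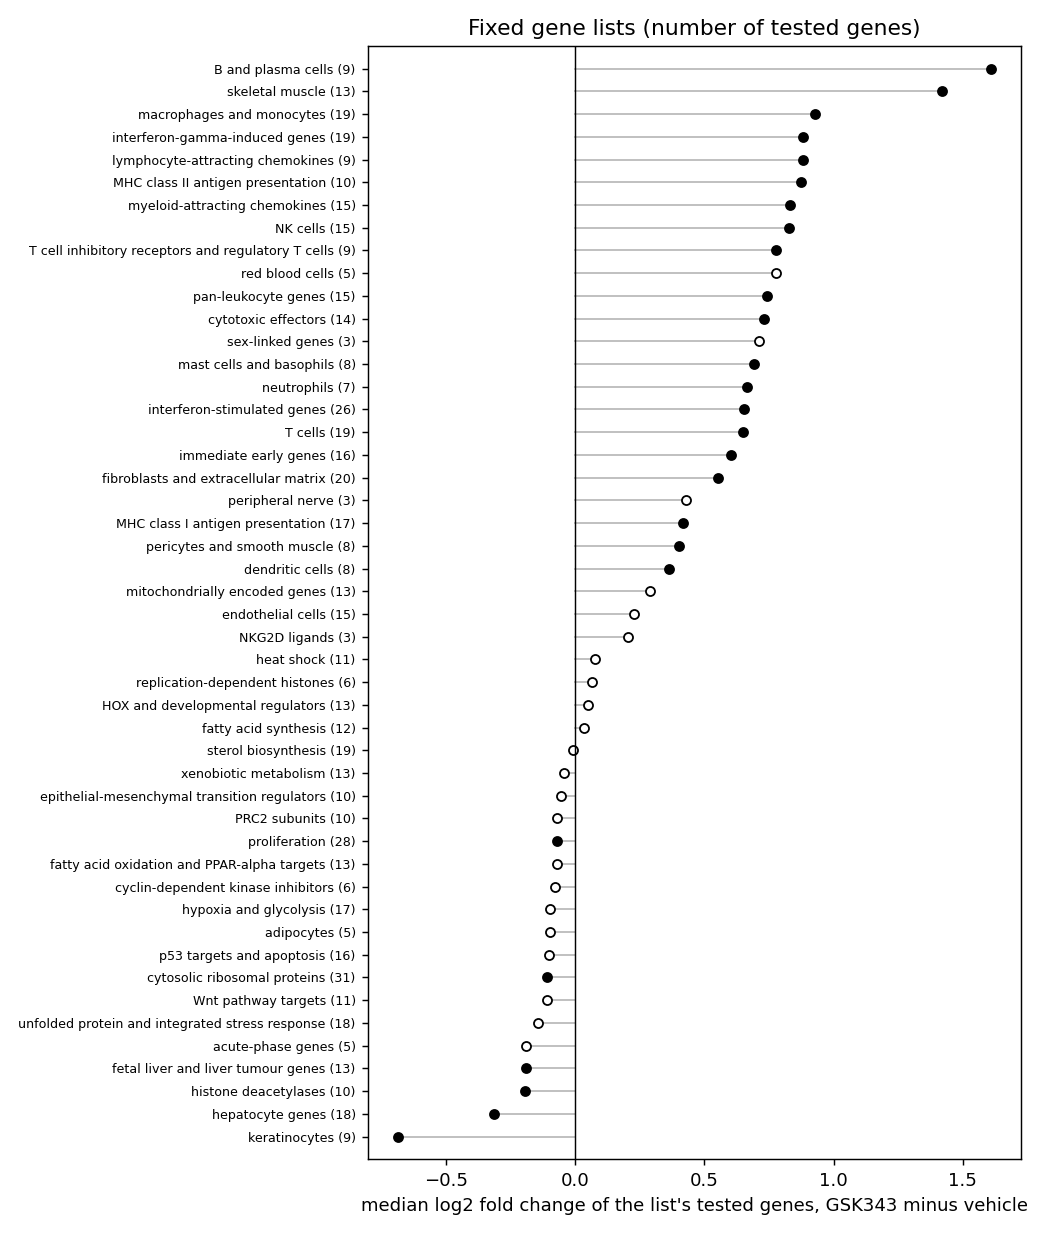
Median log2 fold change (GSK343 minus vehicle) of the tested genes of each of the 48 lists, with filled points for the 26 lists called by camera at the preset correlation and open points for the others. Skeletal muscle and B cell lists lie highest, and none of the filled points was called with an estimated correlation.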

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

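The tests of splits by unadjusted p, of macrophage against endothelial scores and of receptor gene sums, the summed lines and the Y-linked covariate were chosen after the results were seen. Of 162 groups of 5 tumours tested for a single distant value, 5 stood out. That is fewer than the share of about 5% that chance gives, so chance may account for them. The hepatocyte score of vehicle replicate 1 was 5.81, against 4.72 to 4.83 in the other vehicle tumours. Ezh2 was 56.3 FPKM in GSK343 replicate 2, against 40.6 to 44.3 in the other GSK343 tumours. Ccl5 was 225.9 FPKM and Xaf1 49.3 FPKM in vehicle replicate 2, above 90.0 and 17.6, the highest of the other vehicle tumours. Thy1 was 86.5 FPKM in GSK343 replicate 4, below 109 to 119 in the others.

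Of 100 splits of the 10 tumours into 5 and 5, the real one included, 2 called as many as 12 genes, under the bound of 5 set beforehand. That argues against chance for this count without excluding it, since several counts were compared on the same splits. The highest other split called 527 genes. It set vehicle replicates 1, 3, 5 and 6 with GSK343 replicate 4 against vehicle replicate 2 with the other GSK343 tumours, and a count so far above 12 points to a structure of the samples. That split left 8 of the 10 tumours on their treatment side and sorted them by pan-leukocyte score, 4.12 to 4.88 on 1 side and 4.93 to 5.64 on the other. For the 26 lists called, 15 splits gave as many and the highest other gave 31, so chance cannot be excluded. For the 17 lists by score, 3 splits gave as many and the highest other gave 23. For the 2547 lines at an unadjusted p under 0.05, 5 splits gave as many and the highest other gave 3386, so chance cannot be excluded for that count.

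Immune and interferon lists were higher in GSK343 tumours. A uniformly larger share of non-tumour cells is argued against as the whole cause, for the macrophage and endothelial genes only. The macrophage score rose relative to the endothelial score by 0.70 (exact permutation p = 0.0317). The rise was 0.60 (exact permutation p = 0.0476) without the 4 of 15 endothelial genes that correlated below 0 with the Y-linked score, 1 of them at -0.019. However, log2(FPKM + 1) understates changes of low genes, and the endothelial score was the lower one (2.87 against 4.82 in vehicle tumours). A uniform gain could thus raise this contrast in part. Adding 1 matters little for the most highly expressed endothelial genes. Among them Pecam1 went from 14.64 to 18.02 FPKM and Plvap from 14.85 to 19.05 FPKM. Esam fell from 42.38 to 37.75 FPKM and Egfl7 from 20.08 to 18.79 FPKM. The macrophage list had a median log2 fold change of 0.93. These values argue against a uniform gain as the whole source of the contrast. A smaller gain shared by both lists stays open. Macrophage and endothelial scores both followed the Y-linked score (Pearson r = 0.95 and 0.94). More leukocytes remain a candidate explanation of part of the interferon-stimulated list, whose median log2 fold change went from 0.65 to 0.29 with the pan-leukocyte score as covariate and to 0.33 with the Y-linked score. It stayed called at the preset correlation (adjusted p = 6.12e-06 and 2.05e-06), while with an estimated correlation it was not called even without a covariate (adjusted p = 0.399), nor with either covariate (adjusted p = 0.916 and 0.844), so that test decides nothing and more host cells cannot be told apart from a response within cells. An effect of GSK343 on the tumours, and the antibody given to each, stay open as untested.

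Immediate early genes were higher in GSK343 tumours. The line missing for Junb is argued against as the whole cause, since the score difference was 0.63 with lines summed and 0.73 without (exact permutation p = 0.0317 with lines summed). With the pan-leukocyte covariate the list's median fell to 0.15 from 0.60. That score itself differed between the groups (exact permutation p = 0.0476). With it the fibroblast median fell alike, to 0.14 from 0.55, while the skeletal muscle median rose to 1.88 from 1.42. More leukocytes thus stay open as a source, but the fall does not single them out. Handling of the tumours before RNA extraction was not tested.

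Short non-coding and pseudogene lines made up part of the called genes. Of the 12 called lines, 4 had under 300 bases of exon, against 393 such short lines and 14098 longer ones tested. Short lines were also over-represented among the 33 lines at an adjusted p under 0.1. Of the 393 short lines 380 lay at 0.1 or more, against 14078 of the 14098 longer ones. A general gain of short transcripts is argued against as the whole cause. Among lines at an adjusted p of 0.1 or more, 380 short ones lay 0.072 above 14078 longer ones in median log2 fold change (bootstrap SE 0.0194). With the lines under that p included the difference was 0.080 (SE 0.0193), against 0.1, the bound set beforehand. Both SEs come from resampling lines and do not measure the spread between tumours. Whether the difference stays under the bound given that spread was not tested. A median cannot speak to a gain of some short lines only. Such a gain, or a small general one, stays open. Genomic DNA is argued against as the whole cause, since summed olfactory and vomeronasal receptor FPKM differed by 0.23 on the log2 scale (SE 0.0872, exact permutation p = 0.0317), against 1.31 for the called pseudogenes; a smaller gain of such reads stays open. More RNA without a poly-A tail cannot be told apart, because 7 such RNAs differed by 0.30 on average with an SE of 0.136 (exact permutation p = 0.0714). Reads shared with parent genes were not tested, and so no biological reading is favoured.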

How the results depend on the processing

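Summed lines, listed zeros left out, all 3 pairs of tumours left out and the Y-linked covariate were chosen after seeing the data. The 12 gene calls became 2 with the replicate block over the 8 tumours with shared numbers, 5 in those 8 without the block (vehicle replicate 6 and GSK343 replicate 4 left out), 6 with no filter, 3 at a mean of at least 5 FPKM, 7 with median-of-ratios scaling, 7 with quantile normalization, 2 with the pan-leukocyte covariate, 2 with the Y-linked covariate, 4 without GSK343 replicates 3 and 5, 6 without vehicle replicates 1 and 3, 33 at an adjusted p under 0.1 and 7 at a log2 fold change of at least 1. Leaving out 1 tumour gave 3 to 98. The other settings gave 12 to 17. All of the 12 genes tested in a setting kept their sign there. The 26 list calls became 8 with the pan-leukocyte covariate (5 higher and 3 lower) and 14 with the Y-linked covariate (7 higher and 7 lower). They became 0 with an estimated correlation and 0 by fry, and leaving out 1 tumour gave 24 to 31. The 6 lists called lower became 3 with quantile normalization, 2 at a mean of at least 5 FPKM (45 lists tested), 1 without vehicle replicates 1 and 3, 3 with the pan-leukocyte covariate and 4 to 8 with 1 tumour left out, which left 20 to 23 called higher. The 17 lists by score became 3 without GSK343 replicates 3 and 5, 5 without vehicle replicates 1 and 3 and 5 without vehicle replicate 6 and GSK343 replicate 4, with fewer samples, and leaving out 1 tumour gave 7 to 20. Beyond fewer samples or genes, the cause was not tested.

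The values gave no sign that the shared replicate numbers 1, 2, 3 and 5 pair the tumours. Deviations of same-numbered tumours correlated at -0.11, -0.33, 0.03 and -0.19, and no tumour correlated best with its own number. So few correlations cannot exclude a pairing. The block fit of those 8 tumours called 2 genes, of which 0 were among the 12, and 28 lists. Without the block the same 8 tumours gave 5 genes, of which 2 were among the 12, and 28 lists, so part of the loss comes with fewer tumours.

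With the pan-leukocyte covariate the sign turned for the T cell list (-0.13), Suz12 (0.035), Eed (-0.037), Ccl5 (-0.23), Raet1e (-0.00090) and Trac (-0.022), and the macrophage list kept a median of 0.030 while camera gave a fall (not called). The cytotoxic list had a median of -0.02 while camera gave a rise (adjusted p = 0.429). With the Y-linked covariate it turned for the T cell list (-0.14, called lower by camera at an adjusted p of 0.0483, with adjusted p = 0.844 at an estimated correlation), Ezh1 (0.00050), Suz12 (0.0088), Eed (-0.031), Ccl5 (-0.20) and Ulbp1 (0.0036). Ezh1 was 0.00053 without vehicle replicates 1 and 3. Ulbp1 was 0.047 in the 8 tumours with or without the replicate block, 0.025 without vehicle replicate 3, 0.043 without GSK343 replicate 3, 0.018 without GSK343 replicate 4 and 0.0099 without GSK343 replicates 3 and 5. The cause was not tested. Depth was inferred, so it set no limit on single values.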

Other observations

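The heat shock genes Hspa1a and Hspa1b, chosen after their values were seen, were uneven in vehicle tumours. Hspa1a measured 1.15, 41.9, 6.06, 1.22 and 1.97 FPKM in vehicle tumours and 32.6, 29.8, 91.8, 14.3 and 38.7 FPKM in GSK343 tumours (log2 fold change 2.75, limma adjusted p = 0.192). Keratins of skin, also chosen after, differed between tumours within a group. Krt14 measured 30.9 and 36.3 FPKM in vehicle replicates 1 and 3, 4.79 FPKM in GSK343 replicate 5 and at most 1.59 FPKM in the other tumours. Ighm, the heavy chain of immunoglobulin M, ranged from 3.23 FPKM in vehicle replicate 1 to 980.0 FPKM in GSK343 replicate 5.

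Y-linked transcripts and Xist were present together, and this was examined after the values were seen. Xist measured 58.0 to 104.9 FPKM, and Ddx3y 1.66 to 8.10 FPKM. The mean log2 value of Ddx3y, Uty, Kdm5d and Eif2s3y was 1.29 ± 0.340 in vehicle and 1.81 ± 0.315 in GSK343 tumours (SD, n = 5; exact permutation p = 0.0476). Over the 10 tumours this score followed the pan-leukocyte score (Pearson r = 0.97, permutation p = 3e-05, adjusted 9e-05; Spearman rho = 0.96, permutation p = 5e-05, adjusted 0.0003), and r was 0.95 without the 2 tumours farthest from the median. Pearson r was 0.95 for the macrophage score (permutation p = 6e-05, adjusted 0.00012; rho = 0.95, p = 0.00013, adjusted 0.0003), 0.96 for T cells (p = 2e-05, adjusted 9e-05; rho = 0.94, p = 0.00015, adjusted 0.0003), 0.94 for endothelial cells (p = 0.00013, adjusted 0.000195; rho = 0.94, p = 0.00021, adjusted 0.000315) and 0.92 for fibroblasts and matrix (p = 0.0002, adjusted 0.00024; rho = 0.90, p = 0.00078, adjusted 0.000936), and without the 2 farthest tumours r was 0.95, 0.94, 0.88 and 0.85. It did not follow the hepatocyte score detectably (r = -0.53, permutation p = 0.114, adjusted 0.114; rho = -0.43, permutation p = 0.221, adjusted 0.221), with r = -0.31 without those 2 tumours. These are all 6 correlations computed, and the Y-linked score itself differs between the groups. A hypothesis is that Y-linked transcripts come from male host cells in tumours of a line that expresses Xist. Under it, host cell content may carry part of the immune differences. The medians left with the Y-linked covariate varied between lists, but no test compared the lists with each other. The interferon-stimulated median was 0.33 with the Y-linked covariate, against 0.65 without, and the list stayed called by camera at the preset correlation. With that covariate the median was 0.04 for natural killer cells (0.83 without), -0.14 for T cells (0.65) and 0.14 for macrophages (0.93). None of these cell lists was still called higher. The sex of the mice and of the line was not tested.

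A change in copy number of the surrounding segment was tested as a source of the 6 protein-coding calls, before any neighbour was examined. Tested neighbours within 1 Mb, 10 to 35 per gene, had a median log2 fold change, signed by the called gene, of -0.0048, against a median size of 1.01 for the called genes. That argues against a shared change of the segment. Sirpb1b had the highest neighbour value at 0.34.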
